A study of Mus musculus with 36 samples.

How the data were processed

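RNA was measured by sequencing in 36 libraries of sorted mouse brain cells, in 18 groups of 2 libraries each: 6 cell populations, labelled Neg, A, B, C, D and E, from each of 3 brain regions, the olfactory bulb, the cortex and the brainstem. Per the labels, the animals were C57/Bl6 mice, the cells were astrocytes in every group, and total RNA was extracted with a column kit. Per the labels, cDNA was made with the NuGEN Ovation V2 system, which primes with both random and oligo d(T) primers, built into libraries with an Illumina DNA preparation kit and sequenced on an Illumina HiSeq instrument. This chemistry does not mark the strand, so reads of overlapping and antisense genes cannot be told apart. The labels do not say what Neg stands for or which antigens separated the populations. They give no replicate numbers, so libraries were numbered within each group in deposited order, and no number pairs libraries across groups. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

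Per the submitters' processing notes, base calls were converted with bcl2fastq 1.8.3, reads were aligned to mm10 with TopHat, and transcript levels were estimated with Cufflinks; the versions of the last pair are not given in the sources used here. Each deposited table lists 63241 transcripts with their position, length, coverage and FPKM (fragments per kilobase of transcript and per unit of mapped fragments), with the interval Cufflinks gave, per the file headers. FPKM is scaled by each library's mapped fragments, so a library in which some transcripts take a large share shows lower values for all others. Cufflinks estimates are not counts, so no count model was used. Of the 10 mitochondrial transcripts, 3 to 7 were without an estimate in 34 libraries, where their number of fragments exceeded the limit of the program, per the status given in the files; only olfactory bulb E replicate 1 and brainstem E replicate 1 have all of them. The list of mitochondrially encoded genes planned before the data were examined was therefore not tested.

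Depth was read from the ratio of deposited coverage to FPKM, which is proportional to the mapped fragments of a library. It ranged from 0.0695 in brainstem E replicate 1 to 4.07 in olfactory bulb B replicate 1. For transcripts near 10 FPKM, the interval deposited by the authors had a median half-width of 53.4% of the value in brainstem E replicate 1, 32.4% in olfactory bulb E replicate 1, and between 9.57% and 15.1% in the other libraries. These intervals cover the counting and assignment error of a single library, not the spread between libraries.

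Transcripts were assigned to GENCODE vM21 genes by position, since mm10 and the GRCm38 assembly of that annotation share coordinates. A transcript was assigned, without regard to strand, when its overlap score with a gene was at least 0.5 and led the next gene by 0.1 or more. Where genes lay within that margin, it went to the protein-coding gene if only 1 of them was protein coding. In this way 53415 of the 63241 transcripts (84.5%) were assigned, holding between 91.7% and 97.4% of the nuclear FPKM of each library. FPKM values were summed per gene, which gave 25608 genes, and 13634 genes with at least 1 FPKM in 2 or more libraries were tested. Paralogs and overlapping genes share reads in ways that Cufflinks resolves by estimation, so values of near-identical genes such as the globins are uncertain.

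Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean for each of the 18 groups, a trend in the variance prior and 18 residual degrees of freedom. Two-sided moderated tests were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Differences are on the log2(FPKM + 1) scale, which understates changes of genes with low values. The comparisons were the mean of A to E minus Neg, each lettered population minus the mean of the other 4 lettered populations, and each pair of regions over the 5 lettered populations, with regions or populations weighted equally. An F test asked whether population differences depended on region. FPKM as deposited was the main scale, and rescaling to a sum of 1000000 and quantile normalization were alternatives, as were a pseudocount of 0.1, no filter on low values, a minimum log2 difference of 1, the transcript with the highest mean per gene, array quality weights, a term for the series of library numbers in the titles, the first series alone and leaving out each library in turn. Rescaling multiplied each library before 1 was added, so the 1 weighed less than as deposited, to a degree that differed between libraries. Their nuclear FPKM summed from 21757 in brainstem E replicate 1 to 144404 in brainstem C replicate 1. Counts after rescaling therefore mix scaling with a lower pseudocount. The number series is not stated to be a batch. The second series holds all libraries of D and E, cortex A replicate 2, brainstem A replicate 2 and brainstem B replicate 2. With a mean per group, the series term rests only on cortex A, brainstem A and brainstem B, the groups that hold both series. Their libraries of the second series held 4330, 6812 and 5951 genes at 1 FPKM or more, against 8056, 8625 and 9938 in the first. A further pair of alternatives was chosen after seeing the data: leaving out the libraries labelled brainstem D replicate 2 and cortex E replicate 2, and leaving out the 8 libraries with fewer than 5000 genes at 1 FPKM or more. The latter leaves no library of brainstem Neg or brainstem E, so it was fitted with terms for population and region in place of a mean per group. The first series alone was fitted in this form too.

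Gene lists for cell types and pathways were fixed before the data were examined and were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over all lists and comparisons. The list of ribosomal protein genes, called the ribosomal list, was taken by symbol (Rpl or Rps and a number). It therefore also holds genes that do not encode ribosomal proteins, such as the kinase genes Rps6ka1, Rps6ka3 and Rps6kb2, and Rps19bp1. The genes of synapse formation by astrocytes and the surface antigens Itgav, Tfrc and Cd63 were listed with knowledge of the published study of these populations, so their direction is not independent evidence. Named genes also followed a rule fixed in advance: in each comparison the 8 called genes with the largest log2 difference in each direction, with a mean of at least 5 FPKM on the higher side and the same direction in all 3 regions or all 5 lettered populations, without predicted genes and small RNAs; up to 4 members of each named list with the smallest adjusted p; the 10 interaction genes with the smallest p; and Aldh1l1 and the 3 surface antigens. Which of these members are printed, and with which levels, was chosen after seeing the values, and some genes that met the rule are not reported here. The fitting steps were tested on simulated data with the real gene means: for A to E against Neg, 32% of genes changed by a log2 difference of 1 and 93% of those changed by 2 were recovered among 13634 genes, with 4.58% false calls. For brainstem against olfactory bulb these shares were 29%, 90% and 4.03%, and for C they were 31%, 94% and 4.58%. The simulated noise was normal and independent between genes and libraries, without shifts of whole libraries. In the real data the library medians spanned 1.96 on the log2 scale, so these shares check the fitting steps and are not the error rates of the real comparisons. Tables were read with pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.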

Results

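The series profiled sorted cells of the mouse brain to compare cell populations within and between brain regions. It holds 36 RNA-seq libraries, 2 for each combination of 6 populations (Neg, A, B, C, D and E) and 3 regions (olfactory bulb, cortex and brainstem). The number of genes at 1 FPKM or more ranged from 2137 to 7513 in the Neg libraries, from 4330 to 9429 in A, from 5951 to 10409 in B, from 8756 to 10029 in C, from 3049 to 8748 in D and from 3022 to 6825 in E. Fragment numbers were not used here, and the relative depth from coverage was lowest in brainstem E replicate 1 and olfactory bulb E replicate 1, at 0.0695 and 0.314, against 1.16 to 4.07 in the other libraries. The library labelled brainstem D replicate 2 and the library labelled cortex E replicate 2 carried olfactory bulb genes, as described with the regions, and kept their labels in every comparison.

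**Figure D1:**
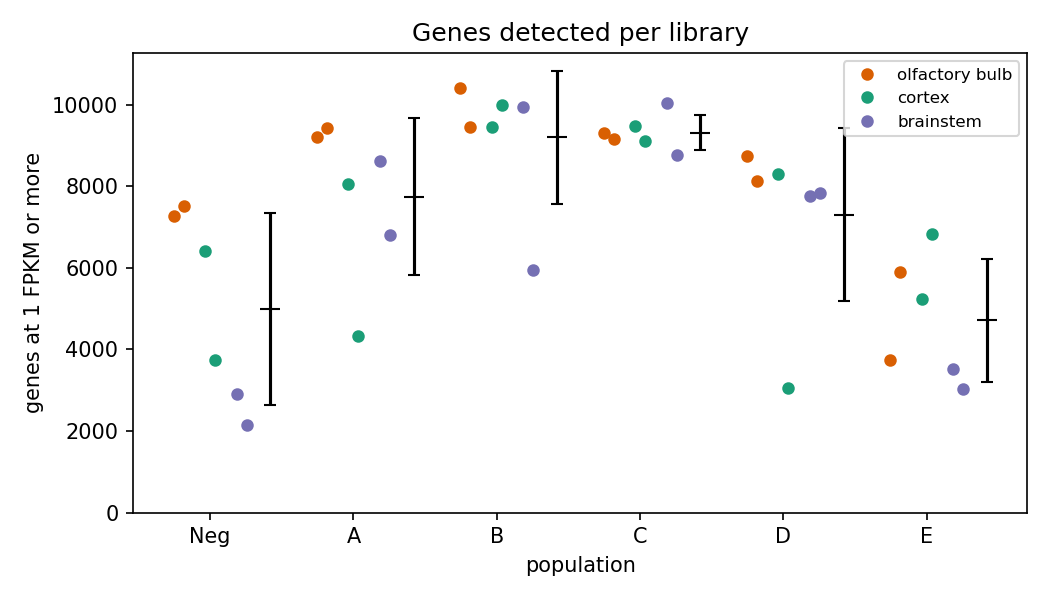
Genes at 1 FPKM or more in each library (vertical axis, number of genes) by population (horizontal axis), with points coloured by region and bars showing the mean and SD of 6 libraries. The C libraries lie between 8756 and 10029 genes, and the E libraries between 3022 and 6825.

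The first comparison asked how the lettered populations differ from Neg. Genes of astrocytes were higher in the mean of A to E, though not in every library. Gpr37l1, a receptor enriched in astrocytes (chromosome 1, 135160234 to 135167681, GRCm38, protein coding), averaged 67.9 ± 59.2 FPKM (SD, n = 30) in A to E and 2.31 ± 2.69 (SD, n = 6) in Neg, a log2 difference of 3.99 ± 0.48 (SE, adjusted p = 1.31e-05). Slc6a11, a GABA transporter of astrocytes, differed by 3.67 ± 0.44 (adjusted p = 1.2e-05), and Apoe, the lipid carrier secreted by astrocytes, by 3.51 ± 0.46 (adjusted p = 2.35e-05). Ntsr2, Cmtm5, Fxyd1, Fabp7 and Ttr completed the 8 largest upward differences that met the naming rule, between 3.54 and 3.94. Aldh1l1, an enzyme of folate metabolism used as a pan-astrocyte marker, was higher by 2.08 ± 0.42 (adjusted p = 0.00161).

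Of 26 astrocyte markers, 26 were higher in A to E, and 26 when adjusted over the list alone, with a median log2 difference of 2.22 (camera adjusted p = 2.69e-25; adjusted p = 0.0979 with an estimated correlation). Slc1a3, the glutamate transporter GLAST, rose by 2.93 ± 0.33, the water channel gene Aqp4 by 2.48 ± 0.31 and the bicarbonate cotransporter gene Slc4a4 by 2.35 ± 0.31. After rescaling and after quantile normalization 15 and 19 of the markers stayed higher and 0 were lower. In some D and E libraries the mean over the list lay within the Neg range, 1.78 to 3.65. These were olfactory bulb E replicate 1 (3.23), brainstem E replicates 1 and 2 (3.10 and 3.33), olfactory bulb D replicate 2 (3.42) and cortex D replicate 2 (3.40). The other lettered libraries lay above it, and the brainstem E means lay above those of brainstem Neg, 2.16 and 1.78. Transmitter uptake genes were higher in 11 of 12 (11 adjusted over the list alone; camera adjusted p = 4.94e-13; adjusted p = 0.113 with an estimated correlation), among them Slc6a9, a glycine transporter, by 2.73 ± 0.40. Cholesterol synthesis genes were higher in 13 of 17 (16 adjusted over the list alone; camera adjusted p = 9.07e-07; adjusted p = 0.317 with an estimated correlation). Within that list Insig1, a regulator of sterol synthesis, differed by 2.42 ± 0.33 and Fdft1, squalene synthase, by 1.96 ± 0.35. Targets of Notch and BMP signalling were higher in 9 of 10 (10 adjusted over the list alone), with camera adjusted p = 5.05e-05 (adjusted p = 0.278 with an estimated correlation). Id3 was at 2.32 ± 0.47 and Id4 at 1.69 ± 0.33. Extracellular matrix and adhesion genes were higher in 13 of 19 (15 adjusted over the list alone; camera adjusted p = 6.5e-05; adjusted p = 0.419 with an estimated correlation), led by Bcan, a proteoglycan of the perineuronal matrix, at 2.85 ± 0.41. Genes of synapse formation by astrocytes, listed with knowledge of the study, were higher in 11 of 22 (14 adjusted over the list alone; camera adjusted p = 0.00055; adjusted p = 0.473 with an estimated correlation). Sparcl1, the synaptogenic protein hevin, was at 2.45 ± 0.33 and Megf10, a phagocytic receptor, at 1.57 ± 0.32. Immediate early and dissociation response genes were higher in 10 of 16 (14 adjusted over the list alone), with camera adjusted p = 0.000817 (adjusted p = 0.548 with an estimated correlation), and in 0 after rescaling and after quantile normalization. Choroid plexus markers were higher in 4 of 7 (7 adjusted over the list alone; camera adjusted p = 0.0469; adjusted p = 0.643 with an estimated correlation). After rescaling and after quantile normalization 8 and 9 transmitter uptake genes were higher, 3 and 4 genes of cholesterol synthesis, 3 and 3 Notch and BMP targets, 3 and 2 matrix and adhesion genes, 3 and 4 genes of synapse formation and 1 and 1 choroid plexus markers. Among these 1 transmitter uptake gene was lower after quantile normalization. Blood cell markers ranked low with 0 of 7 called (0 adjusted over the list alone), at a median of 0.06 and a mean of -0.14 (camera adjusted p = 0.00101; adjusted p = 0.349 with an estimated correlation).

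Among the 20 genes higher in Neg were Rapgef4, Rims1, Camk2a and Sh3gl3, genes of neuronal signalling and the presynaptic terminal, which differed by -1.25 ± 0.36, -1.18 ± 0.39, -1.07 ± 0.38 and -1.34 ± 0.43, and Mobp, a myelin protein gene, by -1.08 ± 0.39. The calls of Mobp (adjusted p = 0.0452) and Camk2a (adjusted p = 0.047) were lost under 23 and 28 of 46 other settings. Cdr1, Kif5b and Zfp365 completed the 8 largest downward differences that met the rule, between -1.13 and -1.05. Of 20 neuron markers 1 was called higher and 0 lower (0 and 0 adjusted over the list alone), while the list as a whole ranked low at a median of 0.07 and a mean of -0.02 (camera adjusted p = 6.8e-07; adjusted p = 0.0944 with an estimated correlation). Celf4 and Nefm, at -0.95 ± 0.40 and -0.77 ± 0.30, did not pass the test (adjusted p = 0.0849 and 0.0661). After quantile normalization 7 neuron markers were lower. Of 14 mature oligodendrocyte markers 3 were higher and 1 lower (4 and 1 adjusted over the list alone), with a median of 0.75 and a camera direction of lower (camera adjusted p = 0.38; adjusted p = 0.89 with an estimated correlation). After rescaling and after quantile normalization 0 of them were higher and 3 lower. With limma, 2763 genes differed, 2743 higher in A to E and 20 lower. The median over all genes was a log2 difference of 0.51, and the split moved to 352 higher and 125 lower of 477 after rescaling and to 411 higher and 563 lower of 974 after quantile normalization, with 290 genes called the same way in all 3 scales. The count was 613 without cortex Neg replicate 2, 954 without brainstem Neg replicate 2, 1347 and 1385 without olfactory bulb Neg replicates 1 and 2, 1640 without brainstem Neg replicate 1, 4224 without cortex D replicate 2, and 316 without the 8 libraries with fewer than 5000 genes.

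**Figure D2:**
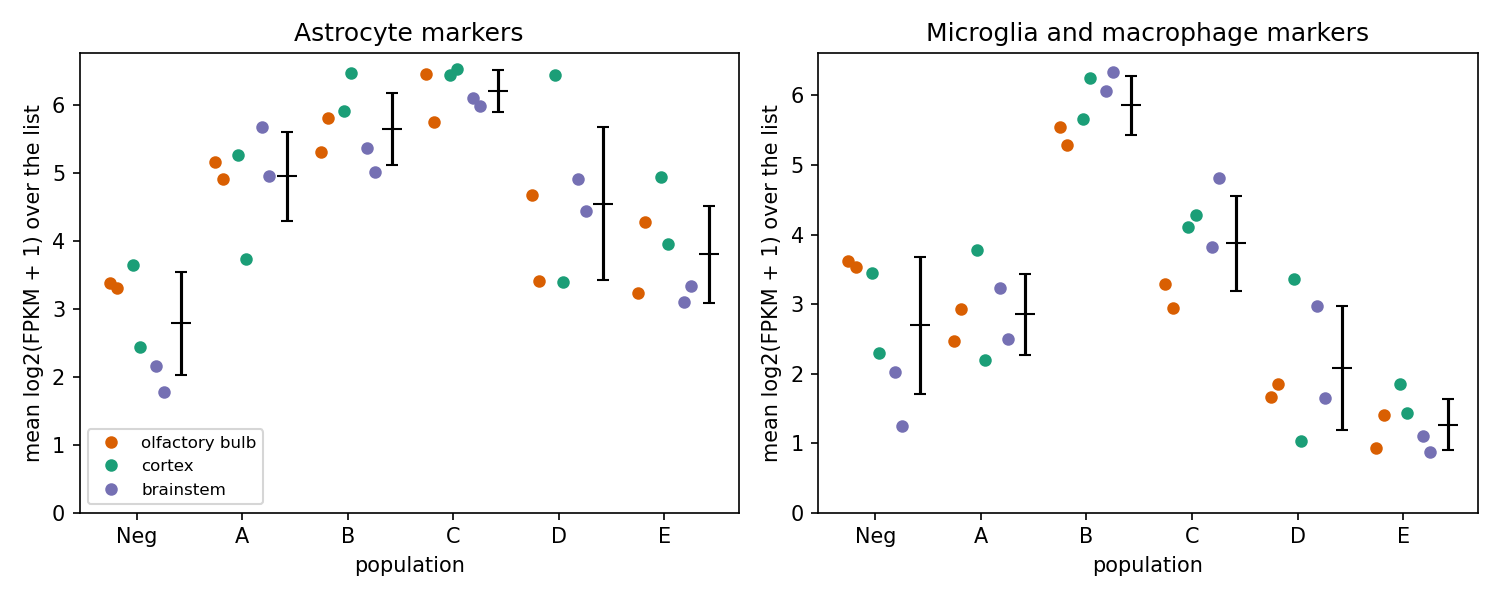
Mean log2(FPKM + 1) over the astrocyte list (left) and the microglia and macrophage list (right) in each library (vertical axes), by population (horizontal axes), with points coloured by region and bars showing the mean and SD of 6 libraries. Microglial means lie between 5.29 and 6.34 in B and between 0.87 and 1.84 in E. Astrocyte means lie between 1.78 and 3.65 in Neg and between 5.76 and 6.53 in C. They lie between 3.40 and 6.44 in D and between 3.10 and 4.93 in E.

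Each lettered population was then set against the mean of the other 4. In A, no single gene passed the test. A pair of hemoglobin genes had the largest values among the blood cell markers, with Hba-a1 at 1.69 ± 0.48 and Hbb-bs at 1.69 ± 0.49 (log2 difference ± SE, adjusted p = 0.999 for both), and Hbb-bs averaged 64.9 ± 51.0 FPKM in A (SD, n = 6) and 22.7 ± 23.7 (SD, n = 24) in the others. The blood list ranked high in A (camera adjusted p = 4.76e-10; adjusted p = 0.0497 with an estimated correlation), with 0 of 7 genes called and 4 higher when adjusted over the list alone. Neuron markers ranked high (camera adjusted p = 7.04e-08; adjusted p = 0.0603 with an estimated correlation; 0 of 20 called and 0 adjusted over the list alone), with the synaptic vesicle gene Syn1 at 0.98 ± 0.41 (adjusted p = 0.999). Microglial markers ranked low (camera adjusted p = 0.000279; adjusted p = 0.457 with an estimated correlation; 0 of 18 called and 1 lower adjusted over the list alone). Trem2, a microglial receptor, was at -1.14 ± 0.30 (adjusted p = 0.796). The other populations include B, which is high in microglial genes, and the microglial list means of the A libraries, 2.19 to 3.78, lay above those of E, 0.87 to 1.84. Aldh1l1 was at -0.17 ± 0.43. By limma, 0 genes were called in A, with 487 genes at an unadjusted p under 0.05, and 0 after rescaling and after quantile normalization, where 629 and 721 genes had an unadjusted p under 0.05. The count was 3, 1 and 10 without olfactory bulb A replicate 1, cortex A replicate 1 and brainstem A replicate 1, 1 without the 8 libraries with fewer than 5000 genes, 15 with no filter on low values and 12 in the first number series, where A was set against B and C and all 12 were lower. The median over all genes was -0.05, and 0.23 after rescaling.

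In B, genes of microglia were higher. C1qc, a complement component made by microglia in the brain (chromosome 4, 136889804 to 136893065, GRCm38, protein coding), averaged 255 ± 56.3 FPKM in B (SD, n = 6) and 26.4 ± 30.7 in the other lettered populations (SD, n = 24), a log2 difference of 4.37 ± 0.46 (SE, adjusted p = 1.23e-07). The chemokine genes Ccl3 and Ccl4 differed by 4.36 ± 0.43 and 4.09 ± 0.41, C1qb and C1qa by 4.04 ± 0.51 and 3.97 ± 0.55, the lysosomal gene Laptm5 by 3.90 ± 0.53, and Trem2 by 3.84 ± 0.30 (adjusted p = 1.46e-09). Of 18 microglia and macrophage markers 18 were higher (18 adjusted over the list alone), with a median of 3.35 (camera adjusted p = 2.82e-31; adjusted p = 0.00724 with an estimated correlation), and 18 were higher after rescaling and after quantile normalization. Csf1r, the receptor that microglia need for survival, differed by 3.55 ± 0.39.

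Immediate early genes, which respond to activity and to tissue dissociation, were higher in B in 16 of 16 (16 adjusted over the list alone; camera adjusted p = 3.7e-18; adjusted p = 0.0956 with an estimated correlation), and in 11 and 13 after rescaling and quantile normalization. The transcription factor genes Atf3, Jun and Egr1 differed by 3.41 ± 0.41, 2.98 ± 0.40 and 2.94 ± 0.39, and Zfp36, which encodes an mRNA decay factor, by 4.18 ± 0.41. Genes of antigen presentation and interferon were higher in 11 of 18 (12 adjusted over the list alone; camera adjusted p = 0.00124; adjusted p = 0.419 with an estimated correlation), and in 5 and 7 after rescaling and quantile normalization. Cd74 and H2-Aa of the class II pathway were at 3.14 ± 0.52 and 3.06 ± 0.38. Both lists were higher in B, like the microglial markers. Whether they vary with these markers between libraries was not tested. Neuron markers were lower in 4 of 20 (4 adjusted over the list alone; camera adjusted p = 4.99e-12; adjusted p = 0.0159 with an estimated correlation), among them Celf4 at -1.56 ± 0.41, Snap25, a protein of synaptic vesicle fusion, at -1.45 ± 0.35, Syn1 at -1.37 ± 0.41 and Rbfox3, the nuclear antigen NeuN, at -0.93 ± 0.31. The calls of Rbfox3 and Syn1 were lost under 15 and 7 of 46 other settings, and those of Celf4 and Snap25 under 3 and 2. Cdr1, Kif5b, Spop, Camk2n1, Usp46 and Kif5a were the other named genes that fell, between -1.68 and -1.42. Aldh1l1 was higher by 1.27 ± 0.43 (adjusted p = 0.0425), and was not called after rescaling or quantile normalization (adjusted p = 0.399 and 0.304), among the 26 of 46 other settings that lost this call. By limma, 2141 genes were called, 2090 higher and 51 lower, against 497 and 124 after rescaling and 544 and 270 after quantile normalization. In all 3 scales 403 genes were called the same way. The median over all genes was 0.35. The count was 1166 without cortex B replicate 2, 1258 without olfactory bulb B replicate 1, and 725 with a term for the number series.

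In C, astrocyte genes were higher as deposited. Slc1a2, the glutamate transporter GLT-1, averaged 941 ± 512 FPKM in C (SD, n = 6) and 374 ± 414 in the other lettered populations (SD, n = 24), a log2 difference of 1.70 ± 0.37 (SE, adjusted p = 0.0147). Aqp4 ranged from 59.9 to 90.4 FPKM in C and differed by 1.46 ± 0.32, Slc1a3 by 1.53 ± 0.34, Fgfr3, a growth factor receptor of astrocytes, by 1.82 ± 0.40 and Aldh1l1 by 1.49 ± 0.43 (adjusted p = 0.0362). Of 26 astrocyte markers 20 were higher (25 adjusted over the list alone; camera adjusted p = 4.94e-13; adjusted p = 0.281 with an estimated correlation), and 0 were called by limma after rescaling or quantile normalization, where 1284 and 1381 of all genes had an unadjusted p under 0.05. The 8 largest differences that met the naming rule were those of Atp5e, Ndufs7, Fmc1, Tmem223 and Grcc10, between 2.33 and 2.61, of which the first 2 encode parts of the respiratory chain and ATP synthase, of Mlc1 at 2.38 ± 0.58 and Cldn10 at 2.33 ± 0.57, membrane proteins of astrocytes, and of Ppp1r1b at 2.34 ± 0.58. The call of Fmc1 was lost under 34 of 46 other settings and its sign turned under 1, with values from -0.21 to 3.09, while the others were lost under 8 to 10.

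Transmitter uptake genes were higher in C in 6 of 12 (11 adjusted over the list alone; camera adjusted p = 6.9e-06; adjusted p = 0.375 with an estimated correlation). Glud1, glutamate dehydrogenase, was at 1.62 ± 0.36. Notch and BMP targets were higher in 6 of 10 (8 adjusted over the list alone; camera adjusted p = 0.00314; adjusted p = 0.419 with an estimated correlation). Hey1 was at 1.74 ± 0.43 and Id4 at 1.45 ± 0.34. Markers of oligodendrocyte precursors were higher in 5 of 13 (8 adjusted over the list alone; camera adjusted p = 0.00811; adjusted p = 0.384 with an estimated correlation). Olig2 was at 1.28 ± 0.34 and Pdgfra at 1.18 ± 0.27. Fibroblast and meningeal markers were higher in 3 of 8 (7 adjusted over the list alone; camera adjusted p = 0.00861; adjusted p = 0.419 with an estimated correlation). Markers of mature oligodendrocytes ranked low (camera adjusted p = 6.9e-06; adjusted p = 0.375 with an estimated correlation; 0 of 14 called and 0 adjusted over the list alone). Genes of synapse formation were higher in 2 of 22 (4 adjusted over the list alone; camera adjusted p = 0.0734). No gene of these lists was called after rescaling or quantile normalization. By limma, 995 genes were called, 994 higher and 1 lower, with a median over all genes of 0.39. After rescaling 1 gene was called, and 5 after quantile normalization, 0 with a term for the number series and 2, both lower, in the first series, and 1 gene was called the same way in all 3 scales. The count was 22, 82, 116, 322 and 458 without olfactory bulb C replicate 1, brainstem C replicate 1, cortex C replicates 1 and 2 and brainstem C replicate 2, 583, 638 and 642 without cortex A replicate 2, brainstem A replicate 2 and cortex B replicate 1, and 1720 and 2626 without brainstem B replicate 1 and cortex D replicate 1.

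In D, microglial genes were lower. Tyrobp, a microglial signalling adaptor (chromosome 7, 30413760 to 30417585, GRCm38, protein coding), averaged 5.19 ± 8.24 FPKM in D (SD, n = 6) and 45.8 ± 47.0 in the other lettered populations (SD, n = 24), a log2 difference of -2.89 ± 0.49 (SE, adjusted p = 0.00977). Trem2 differed by -1.77 ± 0.30 (adjusted p = 0.00977), Csf1r by -1.87 ± 0.39, the Fc receptor gene Fcgr3 by -1.77 ± 0.31, the leukocyte gene Cd37 by -1.92 ± 0.37, H2-Aa by -1.85 ± 0.38 and the interferon receptor gene Ifngr1 by -1.60 ± 0.33. The calls of Csf1r, H2-Aa and Ifngr1 were lost under 34, 32 and 31 of 45 other settings, and those of Tyrobp, Trem2, Fcgr3 and Cd37 under 6, 5, 5 and 12. Of 18 microglial markers 3 were lower, and 15 when adjusted over the list alone (camera adjusted p = 8.12e-19; adjusted p = 0.0497 with an estimated correlation), with 0 called after rescaling and 4 lower after quantile normalization. The other populations include B, which is high in these genes. Endothelial markers ranked high (camera adjusted p = 8.42e-06; adjusted p = 0.128 with an estimated correlation), with 0 of 12 called and 2 adjusted over the list alone, Ly6c1 at 1.30 ± 0.39 (adjusted p = 0.251) and Slco1a4, a blood-brain barrier transporter, at 1.07 ± 0.31 (adjusted p = 0.229). Tmsb15b2 was higher by 1.47 ± 0.30 (adjusted p = 0.0412), a call lost under 35 of the 45. By limma, 15 genes were called, 5 higher and 10 lower, against 0 after rescaling, where 889 genes had an unadjusted p under 0.05, 8 higher and 7 lower after quantile normalization, and 0 with a term for the number series. The median over all genes was -0.08. The count was 217, 95, 34 and 26 without cortex D replicate 1, brainstem D replicate 1, cortex D replicate 2 and brainstem B replicate 1. It was between 5 and 9 without any one of olfactory bulb Neg replicate 1, brainstem Neg replicates 1 and 2, olfactory bulb A, brainstem A and olfactory bulb B replicates 1 and 2, cortex A replicates 1 and 2, cortex B replicate 2, olfactory bulb C replicate 1, cortex C replicates 1 and 2, brainstem C replicate 2, olfactory bulb D replicate 1, olfactory bulb E replicate 2, cortex E replicate 1 and brainstem E replicates 1 and 2.

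In E, most called genes were lower, and the microglial and immediate early genes that were high in B were among the lowest. C1qc averaged 1.32 ± 1.56 FPKM in E (SD, n = 6) and 89.8 ± 104 in the other lettered populations (SD, n = 24), a log2 difference of -4.41 ± 0.46 (SE, adjusted p = 2.14e-06). Fcer1g, C1qb and Ccl3 differed by -4.33 ± 0.50, -4.13 ± 0.51 and -3.60 ± 0.43, Zfp36 by -3.63 ± 0.41, and Atp5e, Romo1 and Ndufb8, which encode mitochondrial proteins, by -3.98 ± 0.63, -3.76 ± 0.57 and -3.60 ± 0.52. Microglial markers were lower in 17 of 18 (17 adjusted over the list alone; camera adjusted p = 4.71e-12; adjusted p = 0.116 with an estimated correlation), and 12 and 10 were lower after rescaling and quantile normalization. Immediate early genes were lower in 15 of 16 (16 adjusted over the list alone; camera adjusted p = 1.42e-09; adjusted p = 0.278 with an estimated correlation), and in 11 and 8 after rescaling and quantile normalization. Nr4a1 was at -2.18 ± 0.31. Astrocyte markers were lower in 20 of 26 (22 adjusted over the list alone; camera adjusted p = 0.000294; adjusted p = 0.628 with an estimated correlation). Slc7a10, an amino acid transporter, was at -2.92 ± 0.47, Fgfr3 at -2.34 ± 0.40 and Aldh1l1 at -1.69 ± 0.43. After rescaling 6 astrocyte markers were lower and 1 was higher, and after quantile normalization 5 and 1.

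Genes of the ribosomal list, which also holds some kinase genes, were lower in E in 50 of 78 (54 adjusted over the list alone, camera adjusted p = 5.02e-05, adjusted p = 0.519 with an estimated correlation). Rpl32 was at -2.80 ± 0.39. Markers of oligodendrocyte precursors were lower in 8 of 13 (8 adjusted over the list alone; camera adjusted p = 0.0289; adjusted p = 0.471 with an estimated correlation). Olig2 was at -2.91 ± 0.34. After rescaling and quantile normalization 30 and 13 genes of the ribosomal list were lower and 1 and 1 higher, and 7 and 3 precursor markers were lower and 0 and 1 higher. Ddx19a, an RNA helicase of mRNA export, was higher by 1.15 ± 0.32 (adjusted p = 0.00658), at 6.78 ± 3.90 FPKM in E (SD, n = 6) and 2.46 ± 1.78 in the others (SD, n = 24), and by 2.77 and 1.90 after rescaling and quantile normalization. The E libraries held 3022 to 6825 genes at 1 FPKM or more. By limma, 5800 genes were called, 17 higher and 5783 lower, with a median over all genes of -0.66, and -1.04 after rescaling. The split was 157 and 3047 after rescaling and 528 and 575 after quantile normalization, and 557 genes were called the same way in all 3. The count was 137 with a term for the number series, 2173 without the 8 libraries with fewer than 5000 genes and 3685 without olfactory bulb E replicate 1.

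Itgav, Tfrc and Cd63, which encode surface antigens, were compared in every population. Itgav, the integrin alpha V subunit, averaged 3.37 ± 2.50 FPKM in Neg, 7.49 ± 2.32 in A, 12.8 ± 4.25 in B, 11.5 ± 3.45 in C, 10.2 ± 3.89 in D and 6.39 ± 3.36 in E (SD, n = 6 each), and was higher in A to E than in Neg by 1.40 ± 0.28 (limma adjusted p = 0.00144). That call was lost under 3 of 46 other settings, with differences from 0.41 to 1.76. Itgav was lower in E by -0.71 ± 0.28 (adjusted p = 0.0455), a direction that turned to 0.29 after rescaling and 0.17 after quantile normalization, and 25 of 45 other settings kept the direction without a call. Tfrc, the transferrin receptor, ranged from 3.59 ± 2.25 FPKM in A to 10.2 ± 9.05 in B and did not differ in any population comparison as deposited, with 0.15 ± 0.34 against Neg (adjusted p = 0.723), where quantile normalization gave -0.80 (adjusted p = 0.0466). Cd63, a tetraspanin of endosomes, ranged from 2.32 ± 1.45 FPKM in Neg to 13.9 ± 5.65 in C and was higher in A to E than in Neg by 1.33 ± 0.44 (adjusted p = 0.0331), without a call after rescaling or quantile normalization (adjusted p = 0.752 and 0.587). Of these 3 antigens 2 were called against Neg (2 adjusted over the list alone). As a list they were not called by camera in any comparison, with a lowest adjusted p of 0.107, and neither were cell cycle genes (0.422), astrocyte reactivity genes (0.0734) or ependymal and cilia markers (0.0873).

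The remaining lists with a camera adjusted p under 0.05 in a population comparison, given here with that p, had an adjusted p = 0.233 or more with an estimated correlation. Against Neg, neural stem and neuroblast markers (0.00784, 1 of 14 higher and 1 adjusted over the list alone) and hindbrain transcription factor genes (0.0478, 0 of 10 called and 0 adjusted over the list alone) ranked low. Their medians were 0.12 and 0.15. In A, genes of the ribosomal list (9.07e-07), neural stem and neuroblast markers (0.00325) and hindbrain transcription factor genes (0.0149) ranked high. Immediate early genes (0.000606), matrix and adhesion genes (0.00492) and mural cell markers (0.00784) ranked low in A, where the other populations include B, which is high in immediate early genes. In each of these lists 0 genes were called by limma and 0 adjusted over the list alone. In B, endothelial markers (0.0405) ranked high with 5 of 12 higher and 7 adjusted over the list alone. Matrix and adhesion genes (0.0288) ranked high with 6 of 19 higher and 10 adjusted over the list alone. After rescaling 0 of both were called, and after quantile normalization 0 and 1. Neural stem and neuroblast markers (0.000168, 0 of 14 called and 0 adjusted over the list alone) and hindbrain transcription factor genes (0.0469, 1 of 10 higher and 1 adjusted over the list alone) ranked low in B. In C, choroid plexus markers (0.015, 2 of 7 higher and 6 adjusted over the list alone) and cholesterol synthesis genes (0.0115, 2 of 17 higher and 5 adjusted over the list alone) ranked high. Neuron markers (0.0141), endothelial markers (0.0494) and immediate early genes (0.00997) ranked low in C at medians of 0.07, 0.11 and 0.16, again with B among the other populations. Of these 0 were called and 0 adjusted over the list alone. Olfactory ensheathing markers (0.0166, 0 of 7 called, 1 higher and 1 lower adjusted over the list alone) also ranked low. Neural stem and neuroblast markers (0.0289) did so too, with 1 of 14 higher and 1 adjusted over the list alone. In D, astrocyte markers (3.84e-05) and transmitter uptake genes (0.0469) ranked low and neuron markers (0.00314) and olfactory ensheathing markers (0.0126) high. Of these 0 were called and 0 adjusted over the list alone. In D genes of antigen presentation and interferon (0.0401) ranked low with 1 of 18 lower and 3 adjusted over the list alone. In E, endothelial markers (0.00805) were lower in 9 of 12, transmitter uptake genes (0.0128) in 10 of 12, cholesterol synthesis genes (0.0126) in 11 of 17 and matrix and adhesion genes (0.0304) in 12 of 19. Adjusted over the list alone the counts were 10, 10, 13 and 14. After rescaling 8, 2, 6 and 6 were lower, and after quantile normalization 0, 1, 2 and 1. Neuron markers (0.000226, 2 of 20 lower and 0 adjusted over the list alone), neural stem and neuroblast markers (0.00111, 2 of 14 lower and 1 adjusted over the list alone) and hindbrain transcription factor genes (0.0334, 0 of 10 called and 0 adjusted over the list alone) ranked high in E. Their medians were -0.31, -0.21 and -0.19. Of the neuron markers 3 were higher in E after rescaling and 3 after quantile normalization.

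The regions were compared over the 5 lettered populations. Genes of the olfactory bulb separated it from cortex and brainstem. Npy, a neuropeptide of interneurons and olfactory ensheathing cells (chromosome 6, 49822710 to 49829507, GRCm38, protein coding), averaged 255 ± 156 FPKM in olfactory bulb, 16.0 ± 46.1 in cortex and 56.9 ± 135 in brainstem (SD, n = 10 each), log2 differences of -6.09 ± 0.64 for cortex (SE, adjusted p = 5.14e-07) and -4.17 ± 0.64 for brainstem (adjusted p = 0.000152). Fabp7, a lipid-binding protein of radial glia and olfactory ensheathing cells, averaged 1906 ± 775 FPKM in olfactory bulb, 250 ± 545 in cortex and 482 ± 1162 in brainstem. Omp, the olfactory marker protein, averaged 16.1 ± 9.30 FPKM in olfactory bulb and 0.103 ± 0.275 in cortex, a difference of -3.76 ± 0.33. S100a5, Stoml3, Clca3a1, Apod and Frzb were also lower in cortex, between -5.20 and -3.68.

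The large SDs in cortex and brainstem came with the library labelled cortex E replicate 2, at 147 FPKM for Npy where the next cortex library had 4.25, and the library labelled brainstem D replicate 2, at 3783 FPKM for Fabp7 where the next brainstem library had 230. Without this pair of libraries limma called 813 genes between cortex and olfactory bulb and 1116 between brainstem and olfactory bulb, so each region direction given here includes libraries whose genes go against the label.

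**Figure D3:**
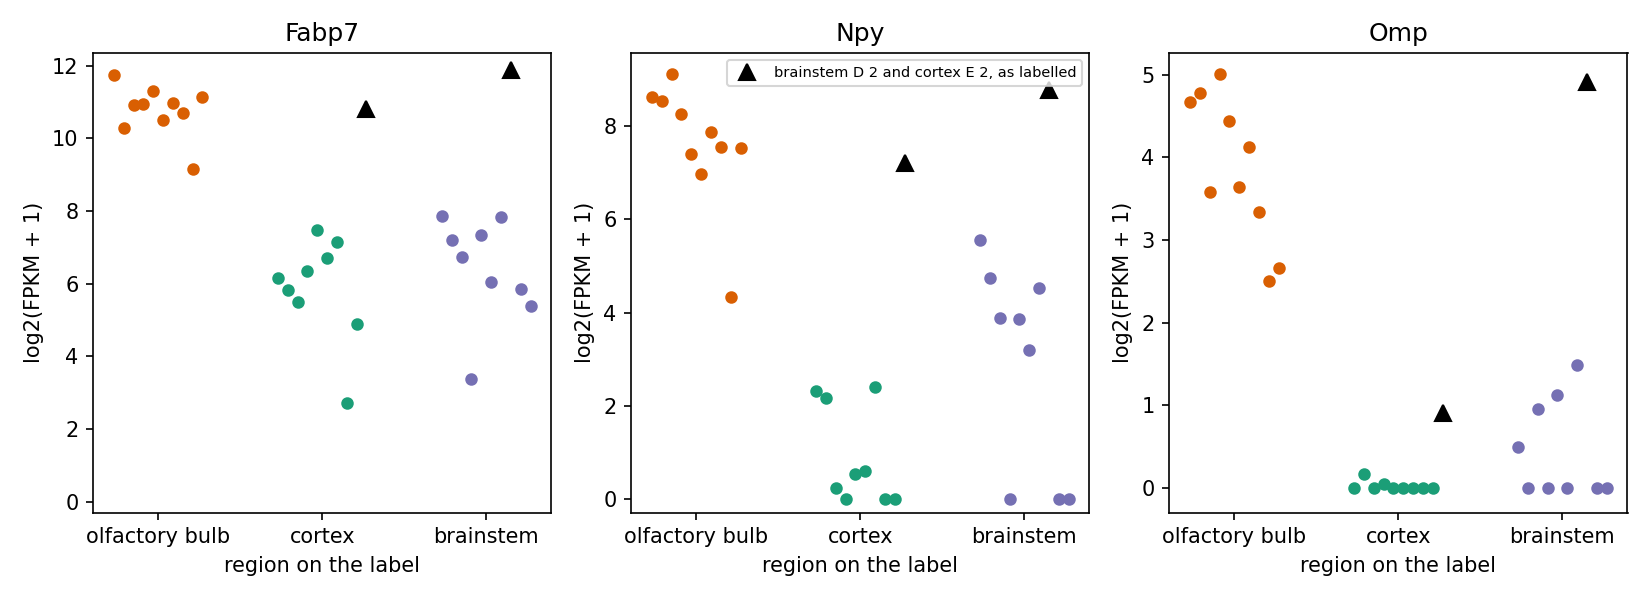
Levels of Fabp7, Npy and Omp as log2(FPKM + 1) in each library of the lettered populations (vertical axes) by the region on the label (horizontal axes). Black triangles mark the libraries labelled brainstem D replicate 2 and cortex E replicate 2; the former holds 3783 FPKM of Fabp7, 440 of Npy and 29.1 of Omp, and the latter 1795, 147 and 0.878, against at least 574, 19.2 and 4.65 in the olfactory bulb libraries.

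Between cortex and olfactory bulb, olfactory ensheathing markers were lower in cortex in 6 of 7 (7 adjusted over the list alone; camera adjusted p = 5.49e-20; adjusted p = 0.00514 with an estimated correlation), with the matrix gene Fbln2 at -2.68 ± 0.37. Neural stem and neuroblast markers were lower in 8 of 14 (10 adjusted over the list alone; camera adjusted p = 1.42e-09; adjusted p = 0.113 with an estimated correlation). Dcx, a microtubule protein of migrating neuroblasts, was at -2.37 ± 0.40 and the interneuron transcription factor genes Dlx1 and Dlx5 at -2.31 ± 0.34 and -2.13 ± 0.32. Higher in cortex were Rims1 at 3.11 ± 0.39, Kif5a at 2.84 ± 0.38, Rph3a at 2.75 ± 0.48 and Kif5c at 2.61 ± 0.38, together with Zfp365 at 2.76 ± 0.35 and Rapgef4 at 2.50 ± 0.36. Of 20 neuron markers 0 were higher and 4 lower (1 and 6 adjusted over the list alone), with camera adjusted p = 0.438 (adjusted p = 0.817 with an estimated correlation). Ttr, the transthyretin made by choroid plexus, was higher by 4.70 ± 1.14 (adjusted p = 0.0135) and Kl, also of choroid plexus, by 2.82 ± 0.49. Choroid plexus markers were higher in 2 of 7 and lower in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 1.31e-05; adjusted p = 0.278 with an estimated correlation). Among 26 astrocyte markers 2 were higher in cortex (2 adjusted over the list alone; camera adjusted p = 3.84e-05; adjusted p = 0.548 with an estimated correlation), Clu, clusterin, by 1.90 ± 0.48 and Slc1a2 by 1.66 ± 0.36. By limma, 514 genes were called, 89 higher in cortex and 425 lower, against 65 and 334 after rescaling and 181 and 307 after quantile normalization. In all 3 scales 276 genes were called the same way. The median over all genes was -0.14, and -0.38 after rescaling. The count was 328 without cortex E replicate 1.

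Between brainstem and olfactory bulb, myelin genes were higher in brainstem. Mag, a myelin glycoprotein gene, averaged 22.5 ± 17.4 FPKM in brainstem and 2.90 ± 4.71 in olfactory bulb (SD, n = 10 each), a log2 difference of 2.81 ± 0.41 (SE, adjusted p = 8.39e-05), and Mbp, myelin basic protein, differed by 2.13 ± 0.36, Enpp2 by 2.72 ± 0.46 and Ermn by 2.23 ± 0.44. Mature oligodendrocyte markers were higher in 9 of 14 (12 adjusted over the list alone; camera adjusted p = 9.85e-19; adjusted p = 0.0497 with an estimated correlation). Dao, D-amino acid oxidase, an enzyme of hindbrain astrocytes (chromosome 5, 114003703 to 114025682, GRCm38, protein coding), averaged 10.1 ± 8.93 FPKM in brainstem and 0.0692 ± 0.0981 in olfactory bulb, a difference of 2.71 ± 0.24 (adjusted p = 4.25e-08). Hindbrain transcription factor genes were higher in 4 of 10 (6 adjusted over the list alone; camera adjusted p = 2.76e-11; adjusted p = 0.00507 with an estimated correlation). Irx1 was at 2.04 ± 0.41, Irx5 at 1.12 ± 0.24 and Pax3 at 0.77 ± 0.16, all listed at 0 in the olfactory bulb libraries. Ttr differed by 5.60 ± 1.14, Kl by 2.80 ± 0.49, the folate receptor gene Folr1 by 2.39 ± 0.49 and Hbb-bs by 2.28 ± 0.48. Choroid plexus markers were higher in 4 of 7 and lower in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 9.7e-08; adjusted p = 0.16 with an estimated correlation).

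Lower in brainstem than in olfactory bulb were S100a5 at -4.59 ± 0.53, Fabp7 at -3.82 ± 0.61, Stoml3 at -3.75 ± 0.55, Doc2g at -3.57 ± 0.42, Clca3a1 at -3.37 ± 0.41, Gad1, the enzyme of GABA synthesis, at -3.18 ± 0.42 and Camk2a at -3.01 ± 0.38. Olfactory ensheathing markers were lower in 5 of 7 (6 adjusted over the list alone; camera adjusted p = 1.02e-10; adjusted p = 0.0497 with an estimated correlation), and mural cell markers were higher in 2 of 11 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00132; adjusted p = 0.142 with an estimated correlation). Telencephalic transcription factor genes were lower in 4 of 12 (4 adjusted over the list alone; camera adjusted p = 0.00656; adjusted p = 0.419 with an estimated correlation). By limma, 716 genes were called, 135 higher in brainstem and 581 lower, against 100 and 620 after rescaling and 280 and 383 after quantile normalization. In all 3 scales 402 genes were called the same way. The median over all genes was -0.19, and -0.53 after rescaling. The count was 439 with a term for the number series and 1113 without brainstem B replicate 1.

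Between brainstem and cortex, Camk2a, a kinase of excitatory synapses (chromosome 18, 60925618 to 60988152, GRCm38, protein coding), averaged 13.7 ± 21.8 FPKM in brainstem and 200 ± 88.4 in cortex (SD, n = 10 each), a log2 difference of -4.58 ± 0.38 (SE, adjusted p = 1.15e-08). Ddn, Hpcal4, Cck, Zfp365, Psd and Ctxn1 differed by -3.89 to -3.15, and Lhx2, a transcription factor of the telencephalon, by -3.36 ± 0.51. Nr2e1, the neural stem cell factor TLX, averaged 0.694 ± 1.07 FPKM in brainstem and 13.7 ± 7.37 in cortex, a difference of -3.13 ± 0.34. Telencephalic transcription factor genes were lower in 5 of 12 and higher in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 1.36e-06; adjusted p = 0.117 with an estimated correlation). Emx2 was at -1.84 ± 0.28. Neuron markers were lower in 5 of 20 (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0163; adjusted p = 0.441 with an estimated correlation). Slc17a7, a vesicular glutamate transporter of cortical neurons, was at -2.36 ± 0.38. Chrdl1, an astrocyte-secreted protein of synapse maturation, fell with 2 other astrocyte markers, by -2.46 ± 0.30 (3 of 26 lower; 5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00997; adjusted p = 0.71 with an estimated correlation).

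Higher in brainstem than in cortex were Gria4 and Gria1, subunits of AMPA receptors, at 2.92 ± 0.38 and 2.39 ± 0.40, Dao at 2.74 ± 0.24, Slc6a9 at 2.37 ± 0.40, Mag at 2.31 ± 0.41, Apod at 2.25 ± 0.52, Itgb4 at 2.01 ± 0.36 and Aldh1a1 at 1.92 ± 0.43. Hindbrain transcription factor genes were higher in 4 of 10 (7 adjusted over the list alone; camera adjusted p = 1.79e-11; adjusted p = 0.00507 with an estimated correlation). Irx2 was at 1.36 ± 0.27 and listed at 0 in the cortex libraries. Mature oligodendrocyte markers were higher in 2 of 14 (6 adjusted over the list alone; camera adjusted p = 1.42e-09; adjusted p = 0.198 with an estimated correlation). By limma, 240 genes were called, 66 higher in brainstem and 174 lower, and 164 were called the same way in all 3 scales, with a median over all genes of -0.03. The count was 427 and 418 without brainstem B replicate 1 and cortex D replicate 2.

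The remaining lists with a camera adjusted p under 0.05 between regions, given here with that p, had an adjusted p = 0.113 or more with an estimated correlation. Between cortex and olfactory bulb, mature oligodendrocyte markers (0.000199, 2 of 14 higher, and 5 higher and 1 lower adjusted over the list alone), microglial markers (2.86e-06, 0 of 18 called) and genes of the ribosomal list (0.0115, 0 of 78 called) ranked high in cortex. Of the last pair 0 were called when adjusted over the list alone. Genes of antigen presentation and interferon (0.00997) ranked low with 3 of 18 lower and 5 adjusted over the list alone. Between brainstem and olfactory bulb, neural stem and neuroblast markers (1.42e-09) were lower in brainstem in 8 of 14 and 11 adjusted over the list alone. Neuron markers (0.00207) were lower in 9 of 20 and higher in 1 (11 and 2 adjusted over the list alone). Endothelial markers (6.98e-05, 2 of 12 higher and 3 adjusted over the list alone) and blood cell markers (0.00018, 1 of 7 higher and 1 adjusted over the list alone) ranked high in brainstem. Microglial markers (1.33e-05) did so with 0 of 18 called and 0 adjusted over the list alone. Fibroblast and meningeal markers (0.0115, 1 of 8 lower, and 1 higher and 1 lower adjusted over the list alone) and immediate early genes (0.0475, 0 of 16 called and 0 adjusted over the list alone) also ranked high. Between brainstem and cortex, olfactory ensheathing markers (0.000141, 1 of 7 higher and 2 adjusted over the list alone) and endothelial markers (0.000279, 1 of 12 higher and 1 adjusted over the list alone) ranked high in brainstem. Mural cell markers (0.015) also ranked high, with 1 of 11 higher and 1 adjusted over the list alone. So did genes of antigen presentation and interferon (0.0026), markers of oligodendrocyte precursors (0.0129) and fibroblast and meningeal markers (0.0392). Of these 0 were called and 0 adjusted over the list alone. Immediate early genes (0.00702) and blood cell markers (0.0171) ranked high with 0 called and 1 higher of each adjusted over the list alone.

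The F test asked which population differences depended on region and called 12 genes. Frzb, a secreted Wnt antagonist of olfactory ensheathing cells (chromosome 2, 80411970 to 80447625, GRCm38, protein coding), averaged 14.4 to 59.0 FPKM in the olfactory bulb groups and 25.5 FPKM in brainstem D and 13.2 FPKM in cortex E, the groups of the 2 libraries that carry olfactory bulb genes (adjusted p = 0.0496). Ndufa4l2, a mitochondrial protein gene, averaged 13.0 FPKM in brainstem B and was listed at 0 in 16 of the 18 groups (adjusted p = 0.0283), and Rtl8c averaged 49.1 FPKM in cortex D and 14.6 in brainstem A (adjusted p = 0.0283). Rtca, Xrcc6, Zfp280b and Mustn1 also passed, with adjusted p between 0.0283 and 0.0496, while Ighm and Ap4m1 did not pass (adjusted p = 0.0526 for both). The calls of Frzb and Mustn1 were lost under 35 and 31 of 44 other settings, and those of the other 5 genes named as passing under 14 to 16 of 41 to 44. Xrcc6 and Ndufa4l2 had a value in 41 and 42 settings. In the remaining ones they did not pass the filter on low values, which is not counted as a loss. Xrcc6 averaged 6.92 FPKM in brainstem B and at most 0.117 in any other group. The count was 3 after rescaling, 1 after quantile normalization and 40 without the libraries labelled brainstem D replicate 2 and cortex E replicate 2. By limma it was 0 without brainstem Neg replicate 1 or 2, olfactory bulb E replicate 2 or brainstem E replicate 2, 1 without cortex B replicate 2, and 2 without cortex Neg replicate 1 or 2, olfactory bulb A replicate 1 or olfactory bulb B replicate 2. It was 117 without brainstem B replicate 1, 55 and 54 without brainstem D replicate 1 and cortex D replicate 1, 31 without cortex E replicate 2, 25 and 24 without cortex D replicate 2 and olfactory bulb D replicate 2, 21 without brainstem A replicate 1, 20 without cortex B replicate 1 or brainstem E replicate 1, and 19 without cortex E replicate 1. In the fit of all libraries 943 genes had an unadjusted p under 0.05.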

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

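The tests of a wrong region label, of a swap, of the replicate 1 libraries, of scaling and cell share in B, of scaling, of the number of genes detected and of the genes also lower than in D in E, and all splits of the samples were chosen only after the result was seen. The rule that reads the test of library complexity was also rewritten more than once after its value was seen, and the loss imposed to check that test was added last.

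Of 90 groups of values, 17 held a library far from the others. The limit used flags about 1 in 20 groups by chance where values are normal. That rate need not hold for groups near 0, such as Dao in cortex with a median of 0. The genes tested were also chosen after their values were seen. The number of genes at 1 FPKM or more was 5951 in brainstem B replicate 2, where the next B library had 9453, and 3049 in cortex D replicate 2. Aldh1l1 was at 8.15 FPKM in olfactory bulb C replicate 2. Tfrc was at 0.810 FPKM in brainstem Neg replicate 1 and 0.401 in cortex D replicate 2. Cd63 was at 0.797 FPKM in brainstem B replicate 2 and listed at 0 in brainstem E replicate 2. Mag was at 16.0 FPKM in olfactory bulb B replicate 1 and 35.0 in cortex B replicate 2. Dao was at 0.327 FPKM in olfactory bulb B replicate 1 and 0.515 in cortex A replicate 1, and Irx1 at 85.2 FPKM in brainstem A replicate 2. Npy was at 19.2 FPKM in olfactory bulb E replicate 1.

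In the library labelled cortex E replicate 2, Npy was at 147 FPKM and Omp at 0.878, and in the library labelled brainstem D replicate 2, Fabp7 was at 3783 FPKM and Omp at 29.1, each far from the other libraries of the labelled region. On a scale from the labelled region (0) to olfactory bulb (1), the lowest of their 4 positions, on olfactory bulb genes and on genes of the labelled region, was 0.718, for cortex E replicate 2 on cortex genes. This argues against a minor share of olfactory bulb RNA mixed into a library of the labelled region. Positions are on a log scale, so a mix that is mostly olfactory bulb RNA stays open for cortex E replicate 2. For brainstem D replicate 2 the positions were 1.11 and 0.954. A swap with an olfactory bulb library of D or E is argued against by the lowest position of those libraries on olfactory bulb genes, 0.835. On genes of cortex or brainstem their lowest position was 0.801. A property of these groups is argued against by the replicate 1 libraries, at most 0.195 on olfactory bulb genes. A wrong region label remains a candidate explanation, from the same 0.718, and the low Omp of cortex E replicate 2 goes against it. No biological explanation other than the property of these groups was tested.

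Microglial genes were higher in B. Scaling as the whole cause is argued against by 18 list genes called higher after quantile normalization, and a lower share of the main cell type by a microglial median 3.85 above the lowest median of the other cell types. That lowest median was of neuron markers, at -1.09, already known to be lower in B, so 3.85 overstates the gap. The microglial median was 2.77. Mature oligodendrocyte, mural, oligodendrocyte precursor and endothelial markers were at 0.69, 0.33, 0.21 and 0.20, and fibroblast and blood markers at -0.04 and -0.27. Of 22 further microglial genes, listed after the pattern was seen but before their values were, 20 were higher in B after quantile normalization, with a median of 2.08, so microglial cells or their RNA in B may contribute. Ctsb and Hk2 were not, and the cathepsins of that list are made by many cells. Expression of these genes by the B cells themselves was not tested and stays open, and a sort against microglial antigens, if used, is not described in the labels.

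Most called genes were lower in E. Of the genes called lower 50.1% stayed lower after rescaling, but rescaling also changed the weight of the 1 added before the log. It therefore cannot decide whether scaling by the library sum was the whole cause. Quantile normalization left 528 higher and 575 lower, 590 of them called the same way as before. A shift of whole libraries that an equal sum does not remove thus stays open. A loss weighted to genes of lower level stays open too. It was taken to put the median of genes of middle level more than 0.2 below that of the highest. The value was 0.114 above for E as a whole, while single E libraries gave -0.22 to 0.04 (SD 0.104), a range that does not hold 0.114, so its direction is not settled. Such a loss imposed on 10 libraries of A to D put it 0.327 above, against 0.0648 above without the loss, opposite to the direction taken. The limit was therefore wrong, and since the E value and its single libraries disagree, the test cannot decide. With the number of genes detected as a term, 0.190% of the calls stayed, the median difference of these genes went from -1.17 to -0.41 and the median SE of all genes from 0.32 to 0.44; this term correlated at 0.974 with the mean level of a library, so it decides nothing, by a limit set after 0.190 was seen. The number series as the cause is argued against for the 589 genes also lower in E than in D, a comparison within the second series that called 3 genes higher and 609 lower, though 4 and 7 after quantile normalization. E against D called 10.6% as many genes. A term for the series left 137 calls for E, but it rests only on groups of A and B and cannot decide. For the other genes the series stays open, as does a biological difference of E.

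The test of whether population differences depend on region called 12 genes, with adjusted p = 0.0283 for Rtl8c, Rtca, Xrcc6, Zfp280b and Ndufa4l2, and 0.0496 for Frzb and Mustn1, calls lost under 35 and 31 of 44 other settings. Mitochondrial transcripts, which no comparison used, summed to 790664 FPKM in olfactory bulb E replicate 1 and 483724 in brainstem E replicate 1. These sums are not comparable with the other libraries, which lack an estimate for 3 to 7 of the 10 transcripts. Over the 3 transcripts estimated in all libraries, the same pair of libraries held 2393 and 6723 FPKM, against 10663 to 85964 in the Neg libraries, 1129 to 6898 in the B libraries and 16898 to 28523 in the other E libraries.

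Random splits of the samples, 100 per comparison with the real one included, used a simpler fit with region or population as a covariate, so the real values differ from the counts given above. The splits exchange single libraries, which may not be separate animals, and ignore the number series, which holds all C libraries on one side and all E libraries on the other. Among such splits the real one called the most genes for cortex against olfactory bulb (1 of 100 splits as large, 344 genes, highest other 0), brainstem against olfactory bulb (1, 575 and 8) and brainstem against cortex (1, 87 and 7), which argues against chance. It also did so for C (1, 22 and 3), on few genes and only as deposited, for A to E against Neg (1, 767 and 745) and for E (1, 4627 and 2373). Other splits with as many as 745 and 2373 genes point to a structure of the samples, so the counts for Neg and E are weaker evidence. After quantile normalization these values were 610 and 208 for Neg, and 913 and 386 for E. The splits by themselves do not exclude the series: with a term for it limma called 0 genes in C, with 658 at an unadjusted p under 0.05, and 137 in E. That term rests only on groups of A and B, so these counts do not decide on the series either. For B, 2 splits were as large (1205 genes), and the highest other called 3026, more than the real count, which points to a structure of the samples; after quantile normalization the values were 706 and 39. The real split called 0 genes with limma for A (highest other 19), for D (43) and for C after quantile normalization (77), so all 100 splits are as large by construction and their number says nothing. For D after quantile normalization 8 of 100 splits were as large (4 genes, highest other 90), so chance cannot be excluded there.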

How the results depend on the processing

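Leaving out the libraries labelled brainstem D replicate 2 and cortex E replicate 2, and leaving out the 8 libraries with fewer than 5000 genes, were chosen only after the result was seen.

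Counts of called genes outside 1.5 times the reported value follow; the cause was not tested except where named. With a pseudocount of 0.1 they were 1327 for B, 129 for C, 5 for D and 0 for the interaction. Without a filter they were 15 for A, 617 for C and 65 for the interaction. Rescaled to a sum of 1000000, they were 477 for A to E against Neg, 621 for B, 1 for C, 0 for D, 3204 for E and 3 for the interaction. After quantile normalization they were 974, 814 for B, 5 for C, 1103 for E and 1 for the interaction. With a term for the number series they were 1 for A, 725 for B, 0 for C, 0 for D, 137 for E, 439 for brainstem against olfactory bulb and 5 for the interaction. With array quality weights, which are equal within each group of 2, they were 5475 for A to E against Neg, 2938 for C, 0 for D, 146 for brainstem against cortex and 0 for the interaction. A minimum log2 difference of 1 gave 3839 for E, by its own construction. The first series alone, where A, B and C are each set against the other 2 and D, E and the interaction give no value, gave 8516 for A to C against Neg, a narrower comparison than A to E against Neg, 12 for A, 661 for B and 2 for C. Its fit had terms for population and region in place of a mean per group, so these counts also differ in the model. The highest transcript per gene gave 1488 for A to E against Neg and 3 for D. Without the pair of libraries at odds with their region label, 813 and 1116 genes differed between cortex or brainstem and olfactory bulb, and 40 in the interaction. Without the 8 libraries with fewer than 5000 genes, the counts were 316 for A to E against Neg, 1 for A, 611 for C, 8 for D and 2173 for E, and the interaction was not run since 2 groups were empty. The empty groups were brainstem Neg and brainstem E, so these counts rest on Neg and E of the other regions and come from a fit of another form.

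Leaving out 1 library at a time, where the lone library of its group is assumed to vary like the others, gave 613 to 4224 for A to E against Neg, 0 to 10 for A, 1166 to 2953 for B, 22 to 2626 for C, 5 to 217 for D, 3685 to 6901 for E, 328 to 751 and 480 to 1113 for cortex and brainstem against olfactory bulb, 163 to 427 for brainstem against cortex and 0 to 117 for the interaction. The libraries behind values beyond 1.5 times are named with each comparison. Of 9421 values of named genes, 8652 kept their side of the threshold, 62 of them with a changed sign in 15 results not called as reported, 718 were weaker, 47 stronger and 4 reversed: Itgav in E at 0.29 rescaled and 0.17 quantile normalized, Tfrc against Neg at -0.80 quantile normalized, and Fmc1 in C at -0.21 with the series term. No paired analysis was possible because the labels give no replicate numbers. The depth of brainstem E replicate 1, 0.0695 against up to 4.07 elsewhere, limits its low values.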
